A study of Mus musculus with 10 samples.

How the data were processed

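Polyadenylated RNA was measured by sequencing in primary mouse hippocampal neurons at 10 days in vitro, 4 libraries from cultures given DMSO and 6 from cultures given tunicamycin at 2 ug/mL, each for 6 h. Libraries were made with a TruSeq RNA v2 kit, which does not mark strand, and read as 50 bp single ends on a HiSeq instrument, per the labels' protocols. FastQC 0.11.5, STAR 2.5.2b, featureCounts, Subread 1.5.1, DESeq2 and the mouse build mm10 are named per the submitters' processing notes, which give them no roles. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here.

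The authors deposited 1 table of whole-number counts per library, each with 48709 Ensembl gene identifiers and no normalization. The deposited counts summed to between 2.11e+07 and 2.92e+07 per library. The authors also deposited tables of upregulated and downregulated genes, each holding a log2 fold change and a p-value with its adjusted form. Every adjusted p in those tables was under 0.05, and the highest was 0.0499. The same deposited tables hold a normalized signal per library. Each of these columns equalled the deposited counts divided by 1 factor per library, within a relative tolerance of 1e-4, for 100% of the listed genes.

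Gene names, types and positions were taken from GENCODE M21 on the GRCm38 assembly, of which mm10 is another name. It matched 48349 identifiers. The 360 unmatched identifiers held 0.046% of the counts and stayed in the library totals. No row of the count tables was without a gene.

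Samples were grouped by the agent in the labels. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit, two-sided) on all 10 libraries, with TMM normalization and the filterByExpr filter, which kept 15660 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are given in CPM, counts scaled to 1e6 per library, as mean ± SD. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. The biological coefficient of variation was 0.049. No library was a repeat of another: chi-square per degree of freedom between libraries of a group was 2.07 to 9.64.

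Before the data were examined, 39 gene lists were fixed, 27 of pathways and 12 of cell types, with 705 members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 38 lists with a tested member. The named genes were also fixed by a rule then. It takes the 6 rising and the 6 falling called genes with the largest log2 fold change, at least 5 CPM in 1 group and no overlap between the libraries of both groups, passing over unnamed gene models and near-identical copies. It adds the 2 members with the smallest p of each list called by camera, 1 of each other list, and Hspa5, Ddit3, Atf4, Xbp1, Dpagt1, Kmt2a, Kmt2d, Kdm5c, Bdnf and Fos. The rule names 80 genes, and results of some items are not reported here. Members of a list that are named because 5 or fewer went against the rest were chosen after their values were seen.

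A gene counted as a near-identical copy when the share of its 50-base words found in transcripts of other genes exceeded the share of its exonic bases overlapping another gene by 10 percentage points or more. This definition was set after the genes that a wider one removed had been seen. The wider one, which also counted genes in overlapping positions, would have passed over Apobr. Among the named genes, 4 are near-identical copies (Hspa8, Hspa1b, mt-Nd4 and Rpl12) and 4 overlap another gene in at least 10% of their exonic bases (Apobr, Ddit3, Nlgn3 and Bdnf). Counts of these 8 may include reads of the other gene and are uncertain.

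The code was tested on simulated counts drawn with the means, spread and sizes of these libraries over the same 15660 genes, with 200 genes changed. The edgeR test recovered 58% of the genes changed 1.25-fold, 86% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and called 6 unchanged genes. Of 60 simulated lists, camera called all 20 raised ones and none of the other 40, with the preset and with an estimated correlation, and fry called all 20 and 4 of the other 40. Each simulated gene was drawn independently, and genes outside the raised lists stayed unchanged. In the real data the correlation estimated for mitochondrially encoded genes was 0.7. The simulation therefore cannot show how the list tests behave with correlated members or a wide response. In the real data 10065 genes were called, which makes the adjusted threshold less strict than with 200 changed genes. The recovered percentages therefore need not hold for the real data.

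The alternatives fixed before the data were examined were DESeq2's size factors, upper-quartile scaling and library size alone in place of TMM, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, a lane term and leaving out each library. For lists they were an estimated correlation and fry. Added after the data were seen were fits of each lane alone, replicates 1 to 4 without the block, list tests after a trend on GC content and length was removed from each library, list tests with upper-quartile scaling, and list tests with the block and an estimated correlation. Lanes 1 to 3 were read from the names of the deposited tables. Lanes 2 and 3 hold 1 DMSO and 2 tunicamycin libraries each, so their fits have 1 residual degree of freedom and assume that the lone DMSO library varies like the others. The median prior degrees of freedom were 13.3 with all libraries, 91.7 in lane 2 and infinite in lane 3, where 12 genes had a p of 0. Counts and p-values of lanes 2 and 3 alone are therefore overconfident, and lanes are compared by fold change.

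For the closing section, the second ratio and the synthetase comparison for Lars2, the bound on the range of astrocyte markers, the widening from 11 to 18 snoRNA hosts, the bound on the spread of coding hosts and the overlap measure without small RNA genes were set after first values had been seen. The bound on coding hosts replaced a comparison with 7 non-coding hosts sharing little sequence, also set after values were seen, under which the test was undecided, because those 7 moved both ways. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.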

Results

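Gene expression was measured in primary mouse hippocampal neurons, cells taken from the hippocampus and grown in culture, at 10 days in vitro. Tunicamycin blocks the first step of N-linked glycosylation, so that newly made glycoproteins misfold in the endoplasmic reticulum (ER). Cultures were given tunicamycin at 2 ug/mL or DMSO, the solvent control, for 6 h. There were 6 tunicamycin and 4 DMSO libraries. Depth was 2.11e+07 to 2.92e+07 counts per library, and 22182 to 23651 genes had at least 1 count. The comparison of both groups addresses how ER stress changes the transcripts of hippocampal neuron cultures. The cultures also held markers of other cells, such as the astrocyte markers Slc1a3 (871 CPM with DMSO) and Gfap (462 CPM). Counts were of whole cultures, so changes cannot be assigned to neurons or to other cells.

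Tunicamycin raised the genes of the ER stress response and the immediate early genes of neuronal activity, and lowered genes of cholesterol synthesis and of astrocytes. As groups these genes passed camera with its preset correlation, and no list passed with an estimated correlation (lowest adjusted p = 0.087). Hspa5, the main Hsp70 chaperone of the ER (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, GRCm38), rose from 616 ± 40.2 CPM (SD, n = 4) to 3206 ± 141 CPM (SD, n = 6). Its log2 fold change was 2.38 ± 0.04 (SE; edgeR adjusted p = 7.65e-20). The largest rises under the naming rule were of Egr2 (log2 4.19), Trib3 (4.10), Apobr (4.03), Gdf15 (3.97), Atf3 (3.71) and Chac1 (3.36). Among the largest falls were those of Mir6236 (log2 -2.84), Lars2 (-2.83), AI464131 (-2.82), Prelp (-2.57) and Aif1l (-2.30). Counts of Mir6236 and Lars2 may come from ribosomal RNA reads, as weighed below for Lars2.

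Of 15660 genes tested, 10065 passed the edgeR test, 4983 higher and 5082 lower with tunicamycin. Under upper-quartile scaling the split was 3632 higher and 6934 lower, because that scaling moved the median log2 fold change of all genes by -0.115. Most called changes were small. Their median was 1.30-fold, and 4270 of them were under 1.25-fold. A change of at least 2-fold was found for 435 genes higher and 333 lower, and of at least 4-fold for 78 higher and 19 lower. All tunicamycin libraries lay on the same side of all DMSO libraries for 51.1% of genes, where chance gives 0.952%. The first principal component held 66.8% of the variance and separated the groups. Fitted alone, sequencing lanes 1, 2 and 3 gave log2 fold changes that correlated with those of all libraries at r = 0.954, 0.916 and 0.894 across genes, the libraries being shared. With lane as a term, edgeR called 9965 genes.

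**Figure D1:**
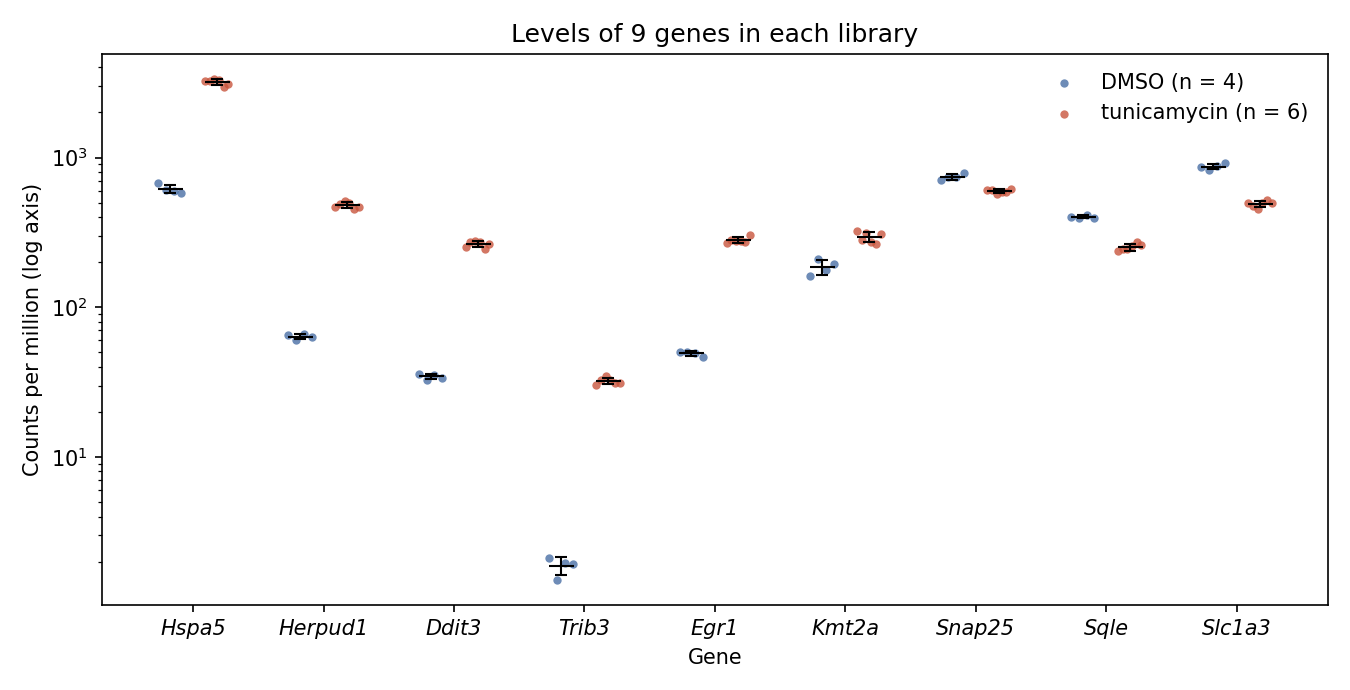
CPM (log axis) of 9 genes in each library, with points for libraries, horizontal lines for group means and bars for 1 SD (DMSO n = 4, tunicamycin n = 6). Hspa5, Herpud1, Ddit3, Trib3, Egr1 and Kmt2a lie higher with tunicamycin in every library, and Snap25, Sqle and Slc1a3 lower.

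The folding machinery of the ER rose almost as a whole. Of 23 ER chaperones and folding enzymes, 21 rose and 1 fell (Dnajc10, log2 -0.40), with a median log2 fold change of 1.19. Creld2, an ER protein that binds misfolded clients, rose from 21.1 ± 0.841 to 180 ± 10.8 CPM, a log2 fold change of 3.09 ± 0.05. Genes of ER-associated degradation, which returns misfolded proteins to the cytosol, rose in 20 of 23 cases, with a median of 0.43. Vcp (log2 -0.17) and Rnf5 (-0.24) fell. Herpud1, a membrane protein of the degradation complex, rose 7.57-fold from 63.8 ± 2.33 to 482 ± 24.0 CPM (edgeR adjusted p = 2.54e-22). The ubiquitin ligase Syvn1 rose 2.87-fold. Of 22 genes of translocation and signal peptide processing, 19 rose, among them Spcs3 (log2 1.02) and Srp68 (0.69), and Srp14 (-0.09) and Spcs1 (-0.16) fell. Of 28 genes of ER to Golgi transport 21 rose, among them the coat proteins Sec23b (1.24) and Sec24d (1.26), and Sar1b (-0.33) and Kdelr1 (-0.28) fell. Camera called all 4 lists higher, with adjusted p of 9.14e-11, 2.19e-07, 1.27e-06 and 8.4e-07 in the order given. With an estimated correlation none was called, with adjusted p = 0.21, 0.12, 0.21 and 0.21.

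Dpagt1 encodes the enzyme that tunicamycin inhibits. It rose 1.78-fold, from 23.3 ± 0.680 to 41.5 ± 1.23 CPM (edgeR adjusted p = 1.83e-13). Of 32 genes of N-linked glycosylation, 21 rose and 5 fell (6 fell when adjusted over the list alone). Alg12, a mannosyltransferase (log2 1.54), and Stt3a, a catalytic subunit of the oligosaccharyltransferase (0.98), were those with the smallest p. The members that fell were Alg14 (-0.36), Dolk (-0.38), Dpm2 (-0.15), Dpm3 (-0.30) and Dad1 (-0.28). Camera's adjusted p was 0.000226, and 0.21 with an estimated correlation. Xbp1, the transcription factor spliced by the ER sensor IRE1, rose 2.44-fold at the gene level, at which its spliced and unspliced forms are not told apart.

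All 20 genes of the ATF4 and CHOP stress response rose, with a median log2 fold change of 2.04. Ddit3, which encodes CHOP, rose from 34.5 ± 1.48 to 264 ± 12.5 CPM, a log2 fold change of 2.93 ± 0.04 (edgeR adjusted p = 2.54e-22). Part of its exonic sequence, 10.9%, overlaps another gene. Atf4 rose 2.61-fold from 227 ± 10.6 to 593 ± 14.5 CPM. Sesn2, a stress-induced inhibitor of mTORC1 signalling, rose 4.73-fold. The pseudokinase Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) rose from 1.88 ± 0.255 to 32.2 ± 1.46 CPM. Amino acid synthesis and transport moved alike, with 20 of 21 genes higher and a median of 1.28. Mthfd2, a mitochondrial folate enzyme, rose 5.14-fold, and Slc7a1, a transporter of cationic amino acids, rose 3.36-fold. Cbs (log2 -0.55) fell. Of 20 cytosolic aminoacyl-tRNA synthetases, 17 rose, with a median of 0.62, among them Iars (1.39) and Cars (1.23), and Qars (-0.16) fell. Camera's adjusted p for these 3 lists was 4.13e-13, 2.29e-11 and 9.18e-08. With an estimated correlation they had adjusted p = 0.087, 0.087 and 0.21.

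All 21 activity-regulated genes rose as well, with a median log2 fold change of 1.22 (camera adjusted p = 2.42e-11, and adjusted p = 0.087 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, rose from 26.9 ± 3.74 to 118 ± 4.43 CPM, a log2 fold change of 2.13 ± 0.07 (edgeR adjusted p = 1.68e-13). Egr1 rose 5.71-fold, Jun 3.80-fold and Egr2 from 1.29 ± 0.212 to 23.4 ± 2.47 CPM. Bdnf, a neurotrophin whose exons overlap another gene in 14.4% of their bases, rose 1.62-fold.

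The histone H3 lysine 4 enzymes moved in both directions. Kmt2a, a methyltransferase of this residue (ENSMUSG00000002028, chromosome 9, 44803355 to 44881296), rose 1.59-fold from 186 ± 20.6 to 294 ± 23.1 CPM, a log2 fold change of 0.67 ± 0.08 (edgeR adjusted p = 3.18e-05). Its relative Kmt2d did not pass the test (log2 -0.06 ± 0.05, edgeR adjusted p = 0.302). Without DMSO replicate 1 it passed, at a log2 fold change of -0.12, and under upper-quartile scaling at -0.18. Of 18 tested members of the methyltransferase complexes, 8 rose (9 when adjusted over the list alone) and 5 fell. Ncoa6, a coactivator subunit, rose 1.66-fold, and the members that fell were Setd1b (-0.42), Dpy30 (-0.19), Men1 (-0.46), Paxip1 (-0.15) and Psip1 (-0.15). The list median was 0.07 and became -0.04 under upper-quartile scaling (camera adjusted p = 0.286). Of 6 demethylases, Kdm5a (0.39), Kdm5b (0.50), Kdm5c (0.26) and Kdm1a (0.10) rose and Kdm2b (-0.27) fell (camera adjusted p = 0.209). Of 20 histone acetyltransferases and deacetylases 10 rose, among them Kat7 (0.78), and Kat2b (-0.28), Hdac1 (-0.64), Hdac3 (-0.17) and Hdac11 (-0.13) fell (camera adjusted p = 0.0862).

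Synaptic genes fell by small amounts, and pan-neuronal markers fell too. Whether these falls differ was not tested. None of 23 presynaptic genes rose and 18 fell, with a median log2 fold change of -0.18. Snap25, a SNARE protein of vesicle release, fell from 742 ± 31.5 to 597 ± 18.8 CPM, a log2 fold change of -0.31 ± 0.03 (edgeR adjusted p = 2.49e-08). Cplx1 fell similarly (-0.33). Of 29 genes of the glutamatergic postsynapse 17 fell, with a median of -0.20. Homer1 (1.12), Dlgap2 (0.78) and Lrrtm2 (0.35) rose, and 5 rose when adjusted over the list alone. Nlgn3, an adhesion protein of the synapse that overlaps another gene in 41.2% of its exonic bases, fell (-0.69). Of 20 plasticity signalling genes 14 fell (16 when adjusted over the list alone), among them the kinases Prkaca (-0.44) and Camkk2 (-0.55), and Creb1 (0.47) and Adcy8 (0.60) rose. Camera's adjusted p for the 3 lists was 0.00036, 0.0168 and 0.0118, and with an estimated correlation they had adjusted p = 0.21, 0.49 and 0.21. Of 100 splits of the libraries, the real one included, 9, 30 and 18 gave a camera p as small, so chance is not excluded for these lists. Some splits keep part of the treatment difference, so these counts do not show chance as the cause either. Voltage-gated ion channels were not called (camera adjusted p = 0.0743). Of 22 members 11 fell, among them Scn2b, a sodium channel subunit, to 0.482 of its DMSO level. Another 3 rose, among them Kcna1 (log2 0.21) and Kcna4 (log2 0.29). That list was called without DMSO replicate 1, under upper-quartile scaling, after removal of a GC and length trend and by fry.

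**Figure D2:**
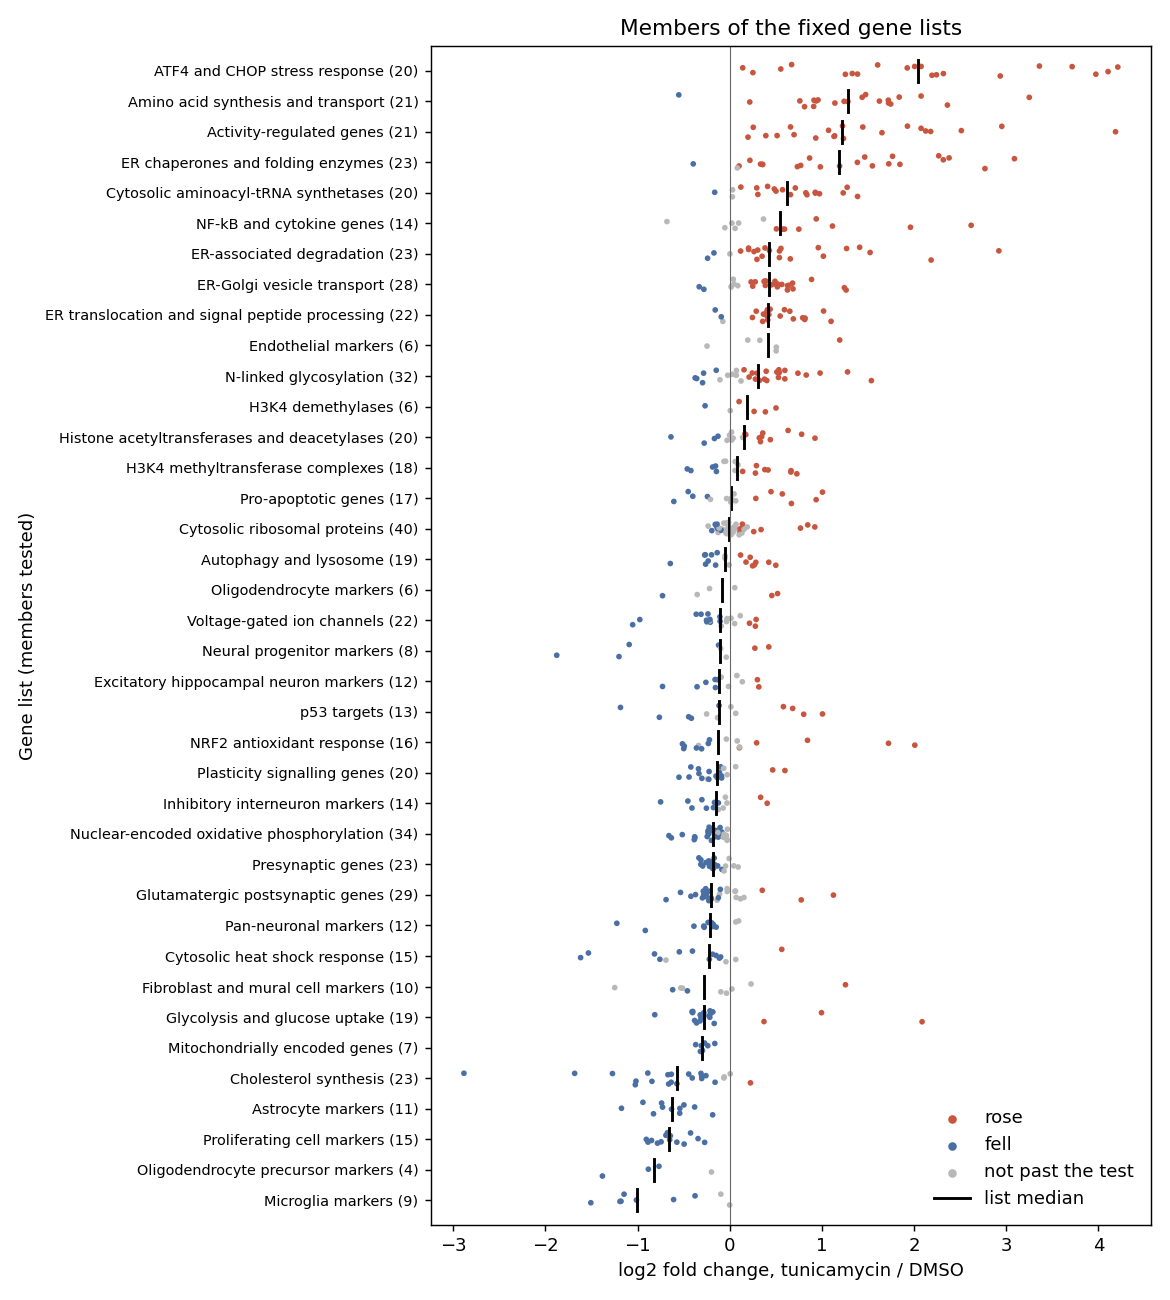
Log2 fold change of each tested member (points) of the 38 gene lists with a tested member, ordered by list median (black lines), with members coloured by the edgeR test at an adjusted p under 0.05. The ATF4 and CHOP list has the highest median (2.04) and the microglia list the lowest (-1.01).

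Cholesterol synthesis fell. Of 23 members 19 fell, with a median log2 fold change of -0.57, and Lss (0.22) rose. The sterol carrier Stard4 (-1.02) and squalene epoxidase, Sqle (-0.67), had the smallest p. Glycolysis and glucose uptake also fell in 16 of 19 members, with a median of -0.28, among them Aldoc (-0.81). Hexokinase 2, Hk2 (log2 2.09), and the glucose transporters Slc2a1 (1.99-fold) and Slc2a3 (log2 0.37) rose. Camera's adjusted p was 7.19e-07 for cholesterol and 0.00406 for glycolysis, and with an estimated correlation adjusted p = 0.31 and 0.4.

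Transcripts of the respiratory chain were lower. Of 34 nuclear-encoded genes 27 fell and none rose, with a median log2 fold change of -0.18, led by the complex II subunits Sdhd (-0.66) and Sdhc (-0.52). The median was -0.11 after a GC and length trend was removed. All 7 tested mitochondrially encoded genes fell, with a median of -0.30, among them mt-Nd1 (-0.31) and mt-Nd4 (-0.27), which has near-identical copies. The mitochondrial share of all counts was 3.75 ± 0.09% (SD, n = 4) with DMSO and 3.19 ± 0.15% (SD, n = 6) with tunicamycin (two-sided exact permutation p = 0.00476, the smallest that 210 splits give, 0.00833 adjusted over 7 library measures). Camera's adjusted p for both lists was 1.33e-05 and 0.00962, and with an estimated correlation adjusted p = 0.4 for each.

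Cytosolic heat shock genes fell in 11 of 15 cases, with a median log2 fold change of -0.22 (camera adjusted p = 0.00289, and adjusted p = 0.12 with an estimated correlation). Hspa8 (-0.82) and Hspa1b (-1.53), both with near-identical copies, had the smallest p, and Hspb8 (0.56) rose. Of 14 NF-kB and cytokine genes 8 rose and none fell, with a median of 0.54 (camera adjusted p = 0.0204, and adjusted p = 0.19 with an estimated correlation). Nfkb1 (0.75) and Cxcl1, a chemokine at 0.272 ± 0.0975 CPM with DMSO (2.62), were those with the smallest p.

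The other pathway lists were not called by camera. Of 17 pro-apoptotic genes 6 rose, among them Bbc3, which encodes PUMA (2.01-fold), and 4 fell, among them Bad (-0.24), Bmf (-0.61) and Casp9 (-0.45). The median of that list was 0.02 and became -0.10 under upper-quartile scaling (camera adjusted p = 0.556). Of 13 p53 targets Bbc3, Cdkn1a (0.58), Mdm2 (0.80) and Eda2r (0.68) rose and 5 fell, namely Ccng1 (-0.42), Trp53inp1 (-1.19), Sesn1 (-0.76), Zmat3 (-0.12) and Perp (-0.45) (camera adjusted p = 0.816). Of 16 NRF2 targets 7 fell and 5 rose (6 when adjusted over the list alone). The 5 were Hmox1, heme oxygenase 1 (log2 2.01), Osgin1 (log2 1.72), Srxn1 (log2 0.84), Gclc (log2 0.10) and Nfe2l2 (log2 0.29). The median of this list was -0.13 and its mean 0.14, with camera pointing lower (adjusted p = 0.583). Of 19 autophagy and lysosome genes 8 rose, among them Atg16l1 (0.42), and 8 fell. Their median was -0.05 and mean -0.0022, with camera pointing higher (adjusted p = 0.992). Of 40 cytosolic ribosomal protein genes 8 rose, among them Rpl12 (0.85), which has near-identical copies, and 6 fell (5 when adjusted over the list alone). Their median was -0.01 and mean 0.06, with camera pointing higher (adjusted p = 0.863).

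Markers of several cell types moved with treatment. All 11 tested astrocyte markers fell, with a median log2 fold change of -0.63, among them the glutamate transporter Slc1a3, from 871 ± 36.2 to 491 ± 23.6 CPM (-0.83 ± 0.04, edgeR adjusted p = 1.4e-14), and glutamine synthetase, Glul (-1.18). All 15 proliferation markers fell, with a median of -0.66, among them Mcm3 (-0.89) and Mcm5 (-0.91), from a median of 9.86 CPM with DMSO. Microglia markers, at a median of 2.07 CPM with DMSO, fell in 7 of 9 cases, with a median of -1.01, among them Tyrobp (-1.19) and C1qc (-1.18). The median of these markers was -0.81, -1.25 and -0.33 in lanes 1, 2 and 3 alone, and the log2 fold change of Tyrobp in lane 3 alone was -0.52. Of 12 pan-neuronal markers 10 fell, with a median of -0.22, among them Nefh (-1.23) and Tubb3 (-0.92). None rose, and 1 rose when adjusted over the list alone. Camera's adjusted p for these 4 lists was 3.07e-05, 0.000134, 0.0215 and 0.00368, and with an estimated correlation they had adjusted p = 0.15, 0.29, 0.4 and 0.27. The microglia list was no longer called with a mean of at least 1 CPM, under upper-quartile scaling or after removal of a GC and length trend.

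Markers of the neuron classes were not called by camera. Of 12 excitatory markers 6 fell, among them Tbr1 (-0.73), and Slc17a6 (0.32) and Wfs1 (0.30) rose (adjusted p = 0.457). Of 14 interneuron markers 8 fell, among them Calb2 (-0.45), and Dlx2 (0.33) and Dlx6 (0.41) rose (adjusted p = 0.0941). Of 4 oligodendrocyte precursor markers Pdgfra (-1.38), Cspg4 (-0.77) and Olig1 (-0.88) fell (adjusted p = 0.131), and that list was called without DMSO replicate 2. Of 6 oligodendrocyte markers Cnp (-0.73) fell and Mog (0.46) and Ermn (0.52) rose (adjusted p = 0.81). Of 8 neural progenitor markers Nes (0.42) and Hes1 (0.27) rose, and 4 fell, among them Sox2 (-0.12), Hes5 (-1.88) and Eomes (-1.09) (adjusted p = 0.261). Of 6 endothelial markers only Flt1 passed the test (1.19, at 0.691 ± 0.248 CPM with DMSO, adjusted p of the list = 0.47). Of 10 fibroblast and mural cell markers Fn1 (1.26) rose and Dcn (-0.46) and Rgs5 (-0.62) fell (adjusted p = 0.6). None of 5 red blood cell markers passed the expression filter.

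Lars2, the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), and the microRNA gene Mir6236 fell with a wide spread between libraries. Counts of both genes may come from ribosomal RNA reads, a candidate explanation weighed below for Lars2. Neither fall is therefore read as one of the named transcript. Lars2 went from 1883 ± 577 to 264 ± 169 CPM (log2 -2.83 ± 0.49, edgeR adjusted p = 0.000866). In lanes 1, 2 and 3 alone its log2 fold change was -1.79, -3.15 and -4.14. Neither gene passed the edgeR test in lane 1 alone or with the replicate block. Lanes 2 and 3 alone rest on 1 DMSO library each, and their p-values are not used. The remaining falling genes were steadier, such as AI464131, from 25.9 ± 1.82 to 3.67 ± 0.534 CPM, and Prelp, a matrix proteoglycan, from 18.5 ± 3.69 to 3.13 ± 0.278 CPM.

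The authors' deposited tables list 4697 upregulated and 4814 downregulated genes. Of these 9511 genes, 9312 (97.9%) were also called here by edgeR, all 9312 in the same direction. Both rest on the same counts, so this overlap is no independent support. Of all genes tested here, 64.3% were called. The authors' deposited table gives log2 fold changes of 2.37 for Hspa5 and 2.93 for Ddit3.

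Camera called 22 of 38 lists, 10 higher and 12 lower, and none with an estimated correlation, where 8 lists had an unadjusted p under 0.05. Counts adjusted over the list alone were the same for 31 lists. For 10 called lists 5 or more of 100 splits of the libraries gave a camera p as small, namely the 3 synaptic and plasticity lists, both respiratory chain lists, NF-kB, glycolysis, pan-neuronal, microglia and proliferation markers.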

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

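The weighing of Lars2 against its other repeat genes and against other synthetases, the test of a lower Lars2 messenger RNA level the scaling test of astrocyte markers and the wider bound on their range were chosen after the results were seen. In 246 group values examined, 10 had a library far from the others of its group by Dixon's gap criterion, where chance gives about 1 in 20, or 12.3.

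In DMSO replicate 1, the highest or lowest library of its group for 5 measures, Nfkb1 stood at 16.66 CPM against 14.21 to 14.61 and Mcm3 at 12 CPM against 10.25 to 10.51. Its mean log2 CPM was 6.512 over ER chaperones against 6.379 to 6.397, 5.355 over NRF2 targets against 5.28 to 5.29, and 7.348 over plasticity signalling genes against 7.431 to 7.437. DMSO replicate 4 had the lowest Egr1, at 46.52 CPM against 49.58 to 50.19. Among tunicamycin libraries, replicate 3 had the highest Syvn1, at 194.1 CPM against 173.1 to 180.2, and the lowest oligodendrocyte markers, at 1.653 against 1.808 to 1.898 (mean log2 CPM). Mean log2 CPM of ER translocation genes was lowest in tunicamycin replicate 5, at 6.301 against 6.383 to 6.414, and of H3K4 demethylases in tunicamycin replicate 4, at 6.358 against 6.416 to 6.45.

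Lars2 fell with 5 genes taken to lie in ribosomal RNA repeats, a placement that was not tested. They were CT010467.1 (log2 -2.35), Mir6236 (-2.84), Gm23935 (-2.56), Gm26917 (-2.39) and Gm15564 (-2.87). Lars2 shared 0.196% and Mir6236 0% of their 50-base words with annotated transcripts of other genes, so that measure shows no link between them. Ribosomal RNA reads counted for Lars2 are a candidate explanation: within the 6 tunicamycin libraries log2 CPM of Lars2 and CT010467.1, an rRNA gene, had Pearson's r = 0.928 (exact permutation p = 0.0111) and Spearman's rho = 0.83 (p = 0.0583), and r = 0.709 without the 2 libraries farthest from the median. With DMSO Lars2 stood at 1283 to 2671 CPM, while 16 other mitochondrial aminoacyl-tRNA synthetases had a median of 19.4 and a highest mean of 67.6 CPM. A lower level of Lars2 messenger RNA in addition stays open: the log2 ratio of Lars2 to CT010467.1 was lower by -0.585 (exact permutation p = 0.019), which met the condition set for it, but against the mean of the other 4 repeat genes the difference was -0.205 (p = 0.0524). Whether less ribosomal RNA came from the cells or from library preparation was not tested.

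Astrocyte markers fell. Under 3 other scalings the highest list median was -0.623, so the fall does not depend on the choice among them. Composition scaling as a cause is not decided by this test. The median log2 fold change of all genes was -0.018 with TMM and -0.133 to -0.00993 under the others. Shifts of that size could not have brought the list to 0. Fewer astrocytes as the whole cause would lower specific markers alike. However, 5 of them ranged from -0.50 for Gja1 to -0.94 for Aqp4, a difference of 0.445 (SE 0.148). It lies beyond 2.73 times its SE, a bound for the range of 5 values with equal SEs and many degrees of freedom. The SEs were 0.142 for Aqp4 and 0.0426 for Gja1, and the fit has 8 residual degrees of freedom. The bound may therefore be too low, and fewer astrocytes as the whole cause is not settled. Fewer astrocytes together with lower expression within them stays open, as does expression of these genes in other cells.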

How the results depend on the processing

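The fits of each lane alone, of replicates 1 to 4 without the block, and the list tests with a GC and length trend removed, with upper-quartile scaling or with the block and an estimated correlation were chosen after the data were seen. The count of 10065 genes was 8847 to 10566 under alternatives that used both groups across all lanes, and leave-one-out fits gave 9593 to 9935. Lanes 1, 2 and 3 alone called 7634, 7577 and 7540, of which the last 2 rest on 1 DMSO library each and are overconfident. The 768 genes changed at least 2-fold were 731 to 829 without 1 library, 574 with a mean of at least 1 CPM and 1253 with no filter, where 30291 genes were tested. Camera called 21 to 23 of 38 lists under the alternatives that kept its preset correlation, 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05, and 0 with the replicate block and an estimated correlation, where 4 did. Fry, which does not compare a list with other genes, called 34. No named gene and no list reversed its direction together with a call. DESeq2 shared 9364 of the edgeR calls, limma-voom 9982 and upper-quartile scaling 8714, each in the same direction. Replicate numbers 1 to 4 occur in both groups, but same-numbered libraries did not deviate together (correlations -0.22 to 0.0085), and 0 of 4 DMSO libraries correlated best with their own number. With the number as a block 8847 genes were called, against 9458 in the same 8 libraries without it, and Lars2 and Mir6236 were not called, and the cause was not tested. Among values of named genes under the alternatives 1828 kept their call or lack of it, 9 lost it, 7 of these in a lane alone (Lars2, Mir6236, Tyrobp, Flt1 and Fn1), and 3 gained it, all of Kmt2d, 1 of these in lane 3 alone. In libraries simulated with the sizes and spread of these and 200 genes changed, 58% of 1.25-fold changes were recovered. With 10065 genes called the adjusted threshold is less strict, so the 58% does not give the share recovered in the real data.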

Other observations

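The pattern of snoRNA host genes was noticed in the data, and the counts of genes over splits of the libraries, the test of shared sequence without small RNA genes and the bound on the spread of coding hosts were chosen after results were seen. Small nucleolar RNAs (snoRNAs) guide the modification of ribosomal RNA and are made from introns of host genes. Of 18 tested non-coding host genes 12 rose and 2 fell, with a median log2 fold change of 0.749. Snhg1 rose from 20.4 to 102 CPM (log2 2.32 ± 0.05 SE), Snhg12 from 13.7 to 63.5 CPM (2.22 ± 0.05), Snhg5 from 24.3 to 101 CPM (2.05 ± 0.05) and Gas5 from 94.2 to 178 CPM (0.92 ± 0.05), while Snhg14 (-0.62) and Cct6a (-0.08) fell. These genes were chosen after their values were seen. Hosts were classed as coding or not by their annotated gene type. Under it Cct6a, at 356 CPM with DMSO, is a processed transcript and counts among the 18. Whether Cct6a encodes a protein was not checked.

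A like rise of hosts of every kind met the bound set against it but is not settled. The 63 protein-coding hosts had a median of 0.0825, with 30 higher and 11 lower. Of all 15660 tested genes, 4983 were higher and 5082 lower. The coding median was below that of non-coding hosts by 0.667, which exceeds the SD of coding hosts (0.401) and not that of non-coding hosts (0.979). These SDs describe the spread of genes and not the error of a median. Coding hosts that share sequence with other genes were not left out. Slower nonsense-mediated decay is consistent with the data as a hypothesis, since many non-coding host transcripts are targets of that decay and mRNAs of its factors are held down by it. Of 8 factors 7 rose, with a median log2 fold change of 0.455, among them Smg1 (0.51) and Smg6 (0.50), and Upf3b stood at -0.05. By the measure set before its value was seen, 61.1% of the 18 hosts shared at least 10% of their sequence with another gene, and for these 11 shared reads cannot be told apart from a rise. The 7 others, whose median of 0.08 is no higher than that of coding hosts, moved both ways: Snhg15 (1.86), 1110038B12Rik (1.59) and 2410006H16Rik (1.55) rose, the last sharing 0% of its sequence, which argues against shared reads as the whole cause, Snhg14 fell and 3 did not pass. With small RNA genes left out, a change made, like the widening from 11 hosts to 18, after a first value was seen, the share was 22.2% and the 14 others had a median of 1.23.

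The real split and others drawn at random from the 210 splits of the 10 libraries into 4 and 6 made 100 splits. Of these, 1 split, the real one, called as many as 10065 genes, and the highest other split called 1. For changes of at least 2-fold, 1 split reached 768 and the highest other called 0. The other splits mix libraries of both groups, so the treatment difference adds to their spread and holds their calls down. The labels do not say that libraries came from separate cultures, so these counts do not exclude a chance difference between cultures. For gene lists, 12 of 100 splits called as many as 22, with a highest other of 24, so that chance cannot be excluded for the number of lists. Splits differ in how much of the treatment difference they keep: 42 splits with 2 DMSO libraries among the 4 called a median of 9 lists and at most 21, and 13 splits with 3 of them called a median of 22. Among the 100 splits drawn, only the real one gave a camera p as small for 8 of the 22 called lists. These were ER chaperones, ER-associated degradation, ER to Golgi transport, ATF4 and CHOP, amino acids, tRNA synthetases, activity-regulated genes and heat shock. For heat shock camera's p was 0.00114, against 0.00177 as the smallest of the other splits. The treatment difference adds to the spread of the other splits, so these counts do not exclude chance for the 8 lists. For 10 called lists 5 or more of the 100 splits gave a p as small: microglia 35, postsynaptic 30, nuclear-encoded respiratory chain 26, mitochondrially encoded 25, proliferation 23, glycolysis 20, plasticity 18, NF-kB 12, presynaptic 9 and pan-neuronal 8. Chance is not excluded for these 10.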
